A study of Danio rerio with 12 samples.

How the data were processed

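Small RNA of whole zebrafish embryos was measured in 12 libraries, 3 for each combination of 36 or 60 hpf and TCDD or DMSO, and each library's group and number were taken from its label. Per the labels' protocols, libraries were made with a small RNA expression kit (SREK) and sequenced on a SOLiD V3 instrument. The deposited values are whole-number counts per feature, 1 table per library, listing only features with at least 1 count, and a feature missing from a library's table was taken as 0. edgeR is named without a version or role in the submitters' processing notes. The aligner, the miRNA annotation release and the genome build are not given in the sources used here, so no coordinates are printed.

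The tables held 699 miRNA rows, of which 352 were star arms, and 1797 rows with Ensembl transcript identifiers, which took 1.20% to 5.35% of each library's counts. None of these identifiers was found in the reference tables at hand, and they were kept out of library sizes and tests of miRNAs. Rows of the same mature name and arm from several hairpin copies mostly carried nearly the same counts: of 65 such sets with a mean total of 1000 or more counts, 46 varied less between copies than independent counting gives (chi-square over the libraries, lower-tail p under 0.001). Reads of these 46 sets had therefore been counted once per copy. For the other 19 this is not shown, and some varied far more (variance over mean 167 for miR-204, 105 for miR-99 and 58.7 for miR-206). Every set was counted once here, by its most abundant copy, which left 464 features. Names were merged only where the copies' counts were alike (a total of at least 80% of that of the most abundant copy). This rule replaced the one written before the data were examined, which took identical rows once and summed all others. It was chosen after the layout of the tables was seen and before any comparison of groups. Under the earlier rule the counts of calls were 0 (TCDD at 36 hpf), 1 (TCDD at 60 hpf, miR-27e), 1 (both times), 0 (difference), 65 (development in DMSO) and 83 (development in TCDD). Near-identical paralogs can still share reads, as the counting rule of the deposited tables is not given in the sources used here.

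Depth was 459634 to 4210840 miRNA counts per library with copies counted once, and 593568 to 5555181 over all rows. Taken over all miRNAs together, counting error was small beside the spread between libraries. For single miRNAs the 2 were not compared. The chi-square of 2 replicate libraries over its degrees of freedom was 215 to 1621, where sampling alone gives about 1. No library was thus a mere resequencing of another. Whether separate libraries were made from the same RNA cannot be told from this.

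Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Features passing filterByExpr (minimum count 10, total 15; 410 kept) were scaled by TMM factors. A model of 4 group means was fitted to all 12 libraries (estimateDisp, glmQLFit with robust=TRUE), and 6 contrasts were tested with glmQLFTest: TCDD against DMSO at 36 hpf, at 60 hpf and averaged over both, the difference of these effects, and 60 against 36 hpf in DMSO and in TCDD embryos. Adjusted p is Benjamini-Hochberg over all tested miRNAs, and a call is an adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of the test's F. CPM values are group means ± SD over 3 libraries. In all, 19 lists of miRNAs were tested with camera (preset correlation 0.01) and beside it with camera at an estimated correlation and with fry, adjusted over the 19 lists: muscle and heart, erythroid, leukocyte, endothelial, clusters of the miR-23a, miR-24 and miR-27a type, smooth muscle, cartilage and mesenchyme, neural, sensory and retina, liver and gut, endocrine, epithelial, miR-430, let-7 timing, miR-17-92 type clusters, Hox clusters, miR-30, miRNAs linked to the aryl hydrocarbon receptor, and stress, p53 and hypoxia. A list holds both arms of its members.

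The comparisons, the main test, the lists, the rule for named miRNAs and the alternative settings other than the 6 named last were fixed before the data were examined. The rule named, for TCDD against DMSO at each time, all calls, filled up by smallest p to 20 miRNAs given by value only. For development in DMSO embryos it named up to 12 per direction of largest change among calls without overlap between libraries and with a mean of 100 CPM or more. For the other contrasts it named the 5 of smallest p, and always the 5 most abundant miRNAs, all members of the cluster, erythroid, muscle and heart, and aryl hydrocarbon receptor lists, and 3 abundant members of each other list. Further members of lists, and miR-193b*, were named after their values were seen.

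The alternative settings were RLE, upper quartile and total count scaling, no filter and a stricter filter (10 or more counts in every library of a group and a mean CPM of 10), DESeq2 1.42.0, limma-voom, edgeR's exact and likelihood ratio tests, robust=FALSE, only the groups compared, a replicate block, each library left out, counts summed per numbered family (131 families) and the 5 most abundant miRNAs left out. Another 6 settings were added after seeing the data. These included every hairpin copy as its own feature, copies summed, transcript rows kept and a replicate block within each treatment. Also added were limma-voom with TCDD libraries of one number correlated between the times (consensus correlation 0.186) and both TCDD libraries numbered 3 left out. Copies summed was the counting rule written before the data were examined, and became an alternative when that rule was replaced. Libraries of one number were checked for pairing by the correlation of their deviations from the group means. Only the TCDD libraries of 36 and 60 hpf passed, at 0.25, 0.26 and 0.42, each correlating best with its own number. This pairing comes from the data, as the labels do not say what the number stands for. Several pairs of groups were checked, and with 3 libraries per group such a match can arise by chance, which was not tested. With that number as a block, development in TCDD embryos gave 80 calls (60 with the block within each treatment) where 88 were called without, and no count of calls of the developmental comparisons changed by more than 1.5 times.

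The test was tested on simulated data, counts drawn with the mean levels, dispersions and library sizes of these libraries, with changes of known size. For TCDD at 60 hpf 68, 64 and 66 miRNAs were changed 2-fold, 4-fold and 8-fold at once and 208 were left unchanged. The other comparisons had similar numbers. For TCDD at 60 hpf it recovered 17.6% of 2-fold, 73.4% of 4-fold and 95.5% of 8-fold changes among 406 tested miRNAs, for TCDD at 36 hpf 18.2%, 75.4% and 89.4% among 405, and for development in DMSO embryos 20.6%, 72.7% and 89.4% among 409. Changes of 2-fold were thus mostly not detectable at this depth and spread. With so many miRNAs changed at once, the Benjamini-Hochberg cutoff is more lenient than where few change. Recovery of a few changed miRNAs was not simulated and would be lower than these shares. Composition was tested by exact two-sided permutation within times (20 labelings, smallest p 0.1) and over both (400 labelings). Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the figures.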

Results

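Small RNAs of whole zebrafish embryos of the TL wild type strain were sequenced at 36 and 60 hours post fertilisation (hpf). Embryos had been exposed to TCDD, a dioxin that activates the aryl hydrocarbon receptor, or to its vehicle DMSO. The 12 libraries fell into 4 groups of 3, and the series title names the question as the response of miRNAs to a short TCDD exposure. The dose and the hours of exposure are not given in the labels used here. Nor do the labels say whether replicates came from separate clutches or pools, so the p-values measure only the spread between these samples. Each library held between 459634 miRNA counts (36 hpf TCDD replicate 3) and 4210840 (60 hpf TCDD replicate 3), a 9.16-fold range. The 36 hpf DMSO libraries held 648934, 1408510 and 3557670 counts, and the 36 hpf TCDD libraries 1236528, 739920 and 459634. At 60 hpf the DMSO libraries held 3738502, 2374864 and 3223999 counts and the TCDD libraries 3207483, 2007639 and 4210840. Levels are given as CPM, counts scaled to library size. A single count was worth 2.18 CPM in the shallowest library and 0.238 CPM in the deepest. Of 464 miRNA features, 410 were abundant enough to be tested, with the arms of a hairpin tested separately. The arm with a star in the deposited names is called the minor arm here, and the other the major arm. A star arm was not always the less abundant one. For miR-199-2* the mean was 146716 counts per copy over all libraries, against 115317 for miR-199.

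The most abundant miRNAs by the mean over all 12 libraries were miR-19b, a member of the miR-17-92 type clusters, at 65712 CPM, and miR-203b, an epidermal miRNA, at 61667 CPM. Their order depended on the group, as miR-19b stood at 21615 CPM and miR-203b at 50481 CPM in TCDD embryos of 60 hpf. Next came miR-130b at 54768 CPM, miR-10c, which lies within a Hox cluster, at 40867 CPM, and the epithelial miR-205 at 39087 CPM. On the first principal component of log2 CPM, which held 34.1% of the variance, the 6 libraries of 36 hpf were separated from the 6 libraries of 60 hpf. The second component (16.2%) set the TCDD libraries numbered 3 apart and the third (11.8%) those numbered 2, at both times. Libraries of a group correlated at 0.902 to 0.970 in log2 CPM.

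At 36 hpf no miRNA passed the test between TCDD and DMSO embryos. The smallest p-value belonged to miR-27e*, the minor arm of the miR-27e hairpin, at 37.7 ± 9.52 CPM in TCDD and 9.55 ± 2.0 CPM in DMSO embryos (SD, n = 3 each; log2 fold change 1.99, SE 0.49, edgeR adjusted p = 0.522). Its major arm miR-27e stood at 51.6 ± 7.95 against 29.0 ± 10.5 CPM (log2 fold change 0.83, SE 0.34, adjusted p = 0.996), and its value was 0.49 without 36 hpf DMSO replicate 2. Further log2 fold changes of small unadjusted p were 1.25 (SE 0.32) for miR-26b*, -0.93 (SE 0.29) for miR-15c, -0.72 (SE 0.26) for miR-455* and -1.52 (SE 0.57) for miR-212. Let-7b stood at 8.45 ± 8.01 against 0.998 ± 1.25 CPM (SD, n = 3), with a spread as wide as its mean. edgeR's quasi-likelihood test called 0 of 410 miRNAs at adjusted p under 0.05, with 17 at unadjusted p under 0.05 where chance alone gives 20.5. DESeq2, limma-voom, edgeR's exact test and its likelihood ratio test each called 0 as well.

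The miRNA lists of tissues and clusters gave no call at 36 hpf, the smallest camera adjusted p being 0.189, for the endothelial and the cartilage lists. All 9 tested endothelial miRNAs had a positive log2 fold change (median 0.35), with miR-126a at 0.49 (SE 1.0), miR-126b* at 1.22 (SE 0.52) and miR-221 at 0.33 (SE 1.29), and none passed the test. Without 36 hpf DMSO replicate 1 this list was called (adjusted p = 0.0363), and without 36 hpf TCDD replicate 1 the stress, p53 and hypoxia list was (adjusted p = 0.00577). Of the 11 tested cartilage and mesenchyme miRNAs, 9 were negative, such as miR-455 at -0.51 (SE 0.30). The muscle and heart miRNAs, among them miR-1 (-0.06, SE 0.42), miR-133a (-0.38, SE 0.48) and miR-206 (0.26, SE 0.48), had a list median of 0.22. The 4 erythroid arms had a median of 0.00, with miR-451 at 0.06 (SE 0.68) and miR-144 at 0.02 (SE 1.53), and no member of either list passed the test. For the erythroid and Hox lists camera's direction was down while their medians (0.00 and 0.04) and means (0.01 and 0.03) were not negative. In the list of miRNAs linked to the aryl hydrocarbon receptor in mammals, 0 of 11 members passed, with miR-132 at 0.17 (SE 0.58), miR-203a at -0.16 (SE 0.26) and miR-21 at -0.99 (SE 0.78). Adjusted over the list alone, only miR-27e* passed in any list at 36 hpf, in the list of miR-23a, miR-24 and miR-27a type clusters.

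At 60 hpf, miR-27e was higher in TCDD embryos. It stood at 134 ± 17.7 CPM in TCDD and 28 ± 1.65 CPM in DMSO embryos (SD, n = 3 each), a log2 fold change of 2.26 (SE 0.34, edgeR adjusted p = 0.0152). The lowest TCDD library, at 115 CPM, lay 3.84 times above the highest DMSO library, at 29.9 CPM. The paralogs miR-27a (0.35, SE 0.43), miR-27b (-0.09, SE 1.08), miR-27c (0.87, SE 1.36) and miR-27d (0.00, SE 0.32) did not pass the test, and miR-27c was nearly absent from 60 hpf TCDD replicate 1, at 2.57 CPM. The minor arm miR-27e* stood at 18.7 ± 10.9 against 8.93 ± 1.49 CPM (log2 fold change 1.07, SE 0.45, adjusted p = 0.656). miR-27e was the 1 call among 410 miRNAs by edgeR's quasi-likelihood test, with 28 at unadjusted p under 0.05.

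**Figure D1:**
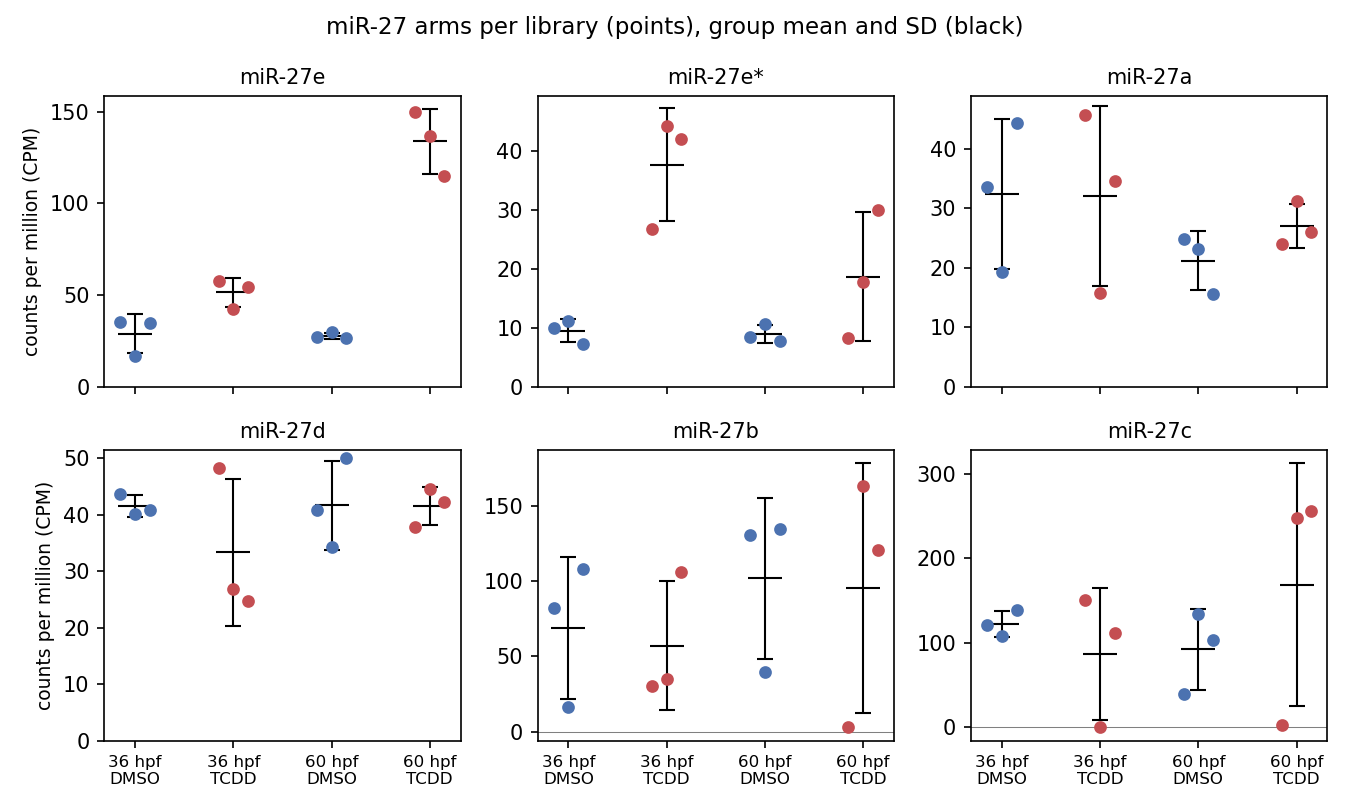
Levels in CPM (vertical axes, linear) of miR-27e, miR-27e* and the paralogs miR-27a to miR-27d in each of the 12 libraries, with points for libraries and black bars for the group mean and SD (n = 3). For miR-27e the 3 TCDD libraries of 60 hpf lie between 115 and 150 CPM and the 3 DMSO libraries between 26.9 and 29.9 CPM, while miR-27c is at 2.57 CPM in 1 TCDD library of 60 hpf.

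Other miRNAs with large values at 60 hpf did not pass edgeR's quasi-likelihood test. The 4 major arms of the miR-19 family were all lower in value, at -1.57 (SE 0.57) for miR-19a, -1.62 (SE 0.74) for miR-19b, -2.0 (SE 0.48) for miR-19c and -2.02 (SE 0.74) for miR-19d. In 60 hpf TCDD replicate 3, miR-19b was at 1843 CPM and miR-19d at 158 CPM, where the next lowest libraries were at 26367 and 2312 CPM. Without that library the values of miR-19a to miR-19d were -1.09, -1.07, -1.69 and -1.47, for a mean of -1.33. With all libraries kept, miR-19c stood at 3668 ± 1479 CPM in TCDD against 14634 ± 3270 CPM in DMSO embryos (SD, n = 3 each, edgeR adjusted p = 0.174). The neural miR-153b stood at 2898 ± 568 against 7628 ± 689 CPM (-1.40, SE 0.37, adjusted p = 0.207), and miR-153c and miR-153a had log2 fold changes of -1.60 (SE 0.42) and -1.08 (SE 0.35). Values of -1.08 were also measured for miR-7a-1 (SE 0.37) and miR-181a (SE 0.39), miRNAs of endocrine, neural and retinal tissue. The pancreatic miR-216b was at 2.74 ± 0.667 CPM in TCDD and at 204 ± 159 CPM in DMSO embryos (-6.17, SE 1.33, adjusted p = 0.159), with a wide spread between DMSO libraries. Positive values included miR-1388 (1.54, SE 0.36), miR-489 (1.90, SE 0.59), miR-454b (4.32, SE 1.65) and miR-24-2* (2.36, SE 0.78). Leukocyte miR-142a and miR-146a had values of -1.03 (SE 0.30) and -1.10 (SE 0.37).

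The call of miR-27e depended on the number of libraries and on how the spread was estimated. With 1 library left out its adjusted p was 0.148, 0.10 and 0.130 without DMSO replicates 1, 2 and 3, and 0.0748, 0.0921 and 0.0388 without TCDD replicates 1, 2 and 3, so 5 of the 6 ended the call, with log2 fold changes from 2.17 to 2.36. Over the other alternatives the adjusted p ran from 5.2e-17 to 0.0998, and it was 0.0525 in a fit of the 60 hpf libraries alone, 0.0640 without both TCDD libraries numbered 3 and 0.0998 with libraries of one number as a block. DESeq2 called 10 miRNAs (4 higher, 6 lower), edgeR's exact test and likelihood ratio test 5 each (2 higher, 3 lower), and limma-voom 1. Those of the exact and likelihood ratio tests were miR-27e, miR-1388, miR-19c, miR-216b and miR-723*, and DESeq2 added miR-142a, miR-153b, miR-153c, miR-454b and miR-489. Scaling by total counts or by the upper quartile moved the median of all miRNAs at 60 hpf by 0.31 and 0.25, so moderate values are given relative to the median miRNA. With TMM factors that median lay at 0.00.

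Among the lists, the miRNAs of the miR-23a, miR-24 and miR-27a type clusters, which are expressed in vessels and heart, were higher as a group at 60 hpf by camera at its preset correlation (adjusted p = 0.00393) but not with an estimated correlation (adjusted p = 0.306), while fry gave 0.0497. Of 20 tested arms 17 were positive (median 0.39), 1 passed the test over all miRNAs and 1 adjusted over the list alone, in both cases miR-27e. Of these arms 12 are star arms (median 0.46) and 8 major arms (median 0.28), and star arms together took 10.5% of the counts in TCDD against 7.12% in DMSO embryos of this time, with 69.8% of the net gain in 3 arms. Over all tested miRNAs the medians were 0.11 for 216 star arms and -0.12 for 194 major arms. Members that did not pass included miR-23a at 0.54 (SE 0.24), miR-23a-1* at 1.0 (SE 0.42) and miR-24 at 0.21 (SE 0.23). Without 60 hpf TCDD replicate 3 the camera adjusted p rose to 0.0686, and without both TCDD libraries numbered 3 to 0.0773, so the call rested on that library. The list median was positive under all 4 scalings at 60 hpf (0.39 to 0.72). Upper quartile and total count scaling also raised the median of all miRNAs, by 0.25 and 0.31, so their higher list medians add no support.

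The remaining lists were not called by camera at 60 hpf. All 4 erythroid arms were negative, with miR-451 at -0.99 (SE 0.69), miR-451* at -1.25 (SE 0.56) and miR-144 at -0.68 (SE 1.53), for a median of -0.83 (camera adjusted p = 0.145). Of 11 leukocyte arms 9 were negative (median -0.37, adjusted p = 0.101). Of 32 arms of the miR-17-92 type clusters 23 were negative (median -0.20, positive at 0.05 and 0.09 with upper quartile and total count scaling; adjusted p = 0.101), and of 17 Hox cluster arms 14 (median -0.48, adjusted p = 0.123). Without 60 hpf DMSO replicate 3 the leukocyte and miR-17-92 type lists were called (both adjusted p = 0.0313), and without 60 hpf TCDD replicate 1 the miR-17-92 type and Hox lists were (0.0122 and 0.0455). In the neural list miR-153b and miR-153c passed as lower adjusted over the list alone, and fry called the list (adjusted p = 0.0497) while camera did not (0.412). Muscle and heart miRNAs had a median of 0.02, with miR-1 at -0.49 (SE 0.42), miR-133a at 0.34 (SE 0.48) and miR-499 at 0.42 (SE 0.47). In the list linked to the aryl hydrocarbon receptor 0 of 11 passed, with miR-132 at 0.06 (SE 0.52), miR-212 at -0.08 (SE 0.43), miR-203a at -0.08 (SE 0.26) and miR-21 at -0.14 (SE 0.77). Its median was -0.08 (0.20 and 0.22 with upper quartile and total count scaling) while its mean was 0.10 and camera's direction was up (adjusted p = 0.759). The sensory and retina list had a median of 0.08 and the liver and gut list one of 0.13, with camera's direction down for both.

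Averaged over both times, miR-27e was again the 1 call among 410 miRNAs, at a log2 fold change of 1.55 (SE 0.24, edgeR adjusted p = 0.0193) and higher than every DMSO library of its own time in 6 of 6 TCDD libraries. Its minor arm miR-27e* followed at 1.53 (SE 0.33, adjusted p = 0.113), then miR-216b at -3.94 (SE 0.85), miR-26b* at 0.94 (SE 0.21) and miR-26a-3* at 0.71 (SE 0.24), none of which passed. At unadjusted p under 0.05 there were 20 miRNAs. DESeq2 and the likelihood ratio test each called 4, adding miR-216b, miR-26b* and miR-27e*. The adjusted p of miR-27e was above 0.05 without 36 hpf DMSO replicate 1 (0.0857), without 36 hpf TCDD replicates 1, 2 and 3 (0.0988, 0.0654 and 0.0829), without 60 hpf DMSO replicates 1, 2 and 3 (0.101, 0.0720 and 0.0918) and without 60 hpf TCDD replicate 2 (0.110). It was also above 0.05 without both TCDD libraries numbered 3 (0.0995) and with a block that pairs TCDD and DMSO libraries of one number within each time (0.120). With TCDD libraries of one number taken as correlated between the times, limma-voom gave 0.0221, and over all alternatives that leave out no single library the range was 1.7e-12 to 0.120. Without 60 hpf TCDD replicate 1, edgeR called miR-27e and miR-27e*. The cluster list of miR-23a, miR-24 and miR-27a was called again (15 of 20 arms positive, 2 adjusted over the list alone, camera adjusted p = 0.0184; adjusted p = 0.462 with an estimated correlation; fry 0.145). That call ended without 36 hpf DMSO replicate 2 (0.0896), without 36 hpf TCDD replicates 1 and 3 (0.0818 and 0.0798), without 60 hpf DMSO replicates 1 and 2 (0.0581 and 0.0744) and without 60 hpf TCDD replicate 3 (0.0756), without both TCDD libraries numbered 3 (0.284) and with the block within each time (0.0916). Without 36 hpf DMSO replicate 3 the erythroid list was called too (0.0494), and without 60 hpf DMSO replicate 3 or 60 hpf TCDD replicate 1 the miR-17-92 type list was (0.0369 and 0.0104).

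The difference of the TCDD effect between the times was tested as an interaction. For miR-27e it was 1.42 (SE 0.47) and did not pass, so its effect at 60 hpf is not shown to differ from that at 36 hpf. The smallest p-values belonged to miR-723* (-4.28, SE 0.95, edgeR adjusted p = 0.388), miR-153b (-1.86, SE 0.51), miR-142a (-1.55, SE 0.43), miR-129-1* (-1.41, SE 0.40) and miR-1388 (1.79, SE 0.51). edgeR's quasi-likelihood test called 0 of 410 miRNAs, with 19 at unadjusted p under 0.05, limma-voom 0, the likelihood ratio test 1 (miR-723*) and DESeq2 6 (these 5 and miR-27e). Without 36 hpf TCDD replicate 3 edgeR called 2, miR-723* (adjusted p = 0.0176) and miR-193b*. Of the lists, cartilage and mesenchyme was higher in the difference (camera adjusted p = 0.0336; adjusted p = 0.488 with an estimated correlation; fry 0.213). Of its 11 arms 9 were positive (median 0.81) and 0 passed alone, with miR-455 at 0.98 (SE 0.43), miR-455b at 1.23 (SE 0.70) and miR-199-3* at 1.90 (SE 1.21). Values of miR-455* and miR-455b* were nearly equal (0.82 and 0.81), so these may not be separate measurements. The list test of the difference was not planned, and camera was not repeated on it with libraries left out.

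The log2 fold changes of TCDD at the 2 times were weakly related across the 410 miRNAs, which are not independent replicates. Pearson's r was 0.24 (permutation p = 0.200 over 400 relabellings within the times) and Spearman's rho 0.15 (p = 0.400), and 53.9% of miRNAs had the same sign. Without 36 hpf DMSO replicate 3 Pearson's r was 0.37 (permutation p = 0.0400).

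Development from 36 to 60 hpf changed many more miRNAs than TCDD did. In DMSO embryos let-7a, a regulator of developmental timing, rose from 72.7 ± 25.3 to 869 ± 262 CPM (SD, n = 3 each; log2 fold change 3.59, SE 0.40, edgeR adjusted p = 0.000385). Among calls with a mean of 100 CPM or more at either time, the arms of miR-190b rose most, miR-190b from 18.9 ± 5.33 to 1052 ± 673 CPM and miR-190b* from 7.16 ± 6.95 to 323 ± 42.8 CPM, by 5.77 (SE 0.65) and 5.33 (SE 0.68) on the log2 scale. miR-430b, of the family that clears maternal mRNA, fell from 759 ± 29.4 to 130 ± 40.0 CPM (-2.55, SE 0.67, adjusted p = 0.0223), and miR-2190 fell from 187 ± 99.6 to 21.9 ± 7.84 CPM (-3.09, SE 0.55). In all, 75 of 410 miRNAs passed, 52 higher and 23 lower at 60 hpf, and DESeq2 called 120. The DMSO libraries of the 2 times did not overlap for 75 of these 75, and for 42.4% of all 410 miRNAs, where chance gives 10%.

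**Figure D2:**
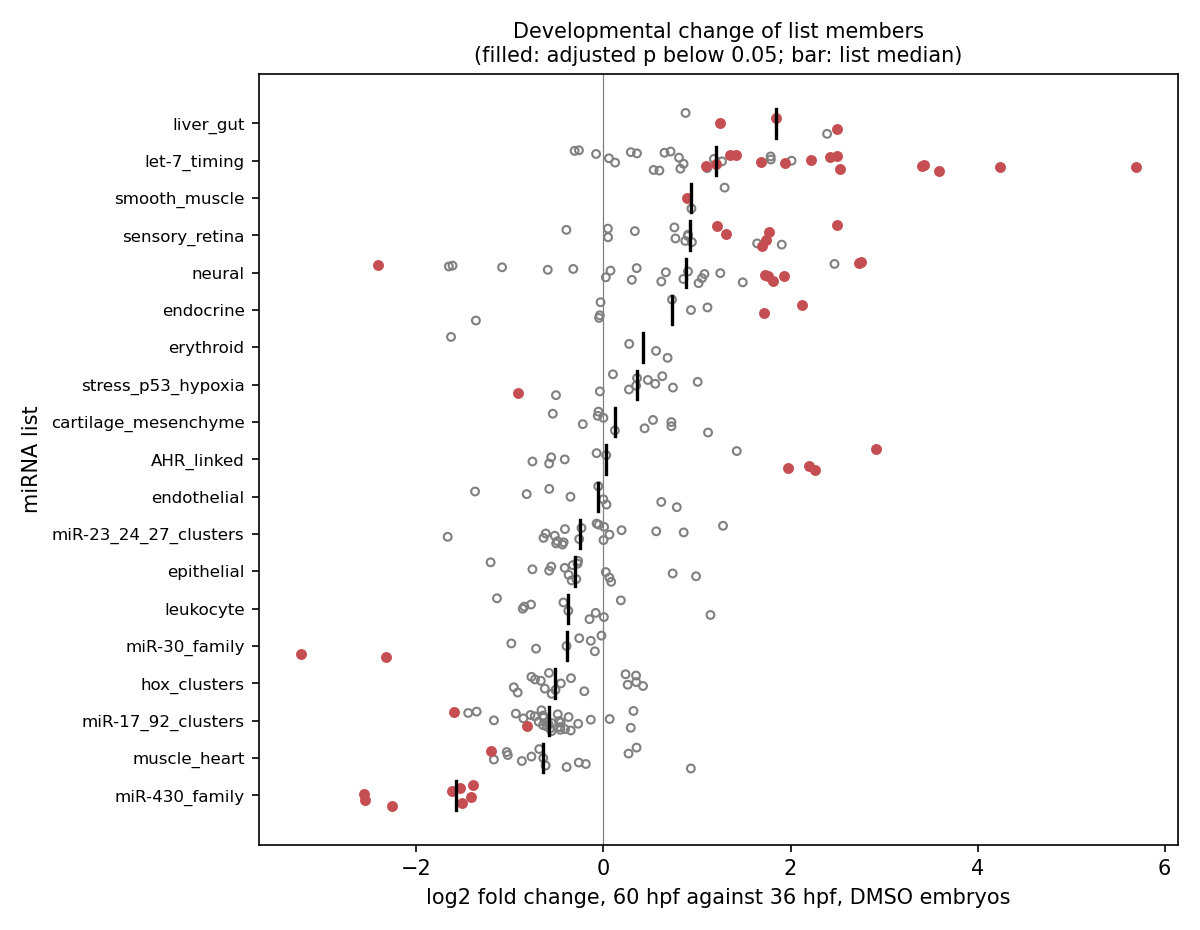
Log2 fold change of 60 against 36 hpf in DMSO embryos (horizontal axis) of each tested member of the 19 miRNA lists (vertical axis), with filled points for adjusted p under 0.05 and a bar at the list median. All 8 members of the miR-430 family lie below 0, and 15 of 35 arms of the let-7 timing list are filled, to the right of 0.

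The let-7 timing list, with let-7, miR-99, miR-100 and miR-125, was higher at 60 hpf. Of 35 arms 15 rose and 0 fell (18 adjusted over the list alone; median 1.20), among them let-7d (3.43, SE 0.37), let-7c (3.41, SE 0.74), let-7a-3* (2.53, SE 0.34) and miR-125a (2.42, SE 0.38), with a camera adjusted p of 4.4e-08 (adjusted p = 0.0672 with an estimated correlation). The sensory and retina list rose too (6 of 18 arms, 6 adjusted over the list alone, 0 fell; camera adjusted p = 0.0197; adjusted p = 0.0773 with an estimated correlation), with the hair cell and photoreceptor miRNAs miR-183 (1.31, SE 0.36), miR-96 (1.22, SE 0.37) and miR-96* (2.50, SE 0.49). miR-181a of the same list was at 1.69 (SE 0.39). In the liver and gut list 3 of 5 arms rose (3 adjusted over the list alone; camera adjusted p = 0.0197; adjusted p = 0.0780 with an estimated correlation): the liver arm miR-122* from 20.7 ± 6.52 to 120 ± 12.2 CPM (2.50, SE 0.33), miR-192 (1.25, SE 0.34) and miR-194a (1.84, SE 0.57). Without 36 hpf DMSO replicate 2 the liver and gut list had an adjusted p of 0.0541. None of these 3 calls held with an estimated correlation, while fry called all 3.

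The miR-430 family was lower at 60 hpf in all 8 of its tested arms (8 adjusted over the list alone; median -1.58, camera adjusted p = 1.4e-06; adjusted p = 0.0773 with an estimated correlation, which ends the call). Besides miR-430b these were miR-430a (-2.27, SE 0.40), miR-430c (-2.57, SE 0.77), miR-430c* (-1.62, SE 0.42), miR-430i* (-1.54, SE 0.33), miR-430a-22* (-1.52, SE 0.33), miR-430b* (-1.42, SE 0.31) and miR-430j* (-1.40, SE 0.33). Several of these star arms are near-identical in sequence and count, so they are not 8 separate measurements. The call of miR-430c ended without each of the 6 libraries in turn (adjusted p = 0.0872, 0.0659 and 0.0573 without 36 hpf replicates 1, 2 and 3, and 0.138, 0.0804 and 0.0994 without 60 hpf replicates 1, 2 and 3). miR-430b lost its call without 60 hpf DMSO replicates 1 and 2 (0.0824 and 0.0740), miR-430c* without 36 hpf DMSO replicate 3 and 60 hpf DMSO replicates 2 and 3 (0.0545, 0.0760 and 0.0720), and miR-430j* without 60 hpf DMSO replicate 2 (0.0520).

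The miR-17-92 type clusters were lower as a group at 60 hpf (29 of 32 arms negative, median -0.58, camera adjusted p = 0.00320; adjusted p = 0.0773 with an estimated correlation), with miR-92b (-1.60, SE 0.47) and miR-18c* (-0.82, SE 0.24) past the test and 0 adjusted over the list alone. The miR-30 family, abundant in the kidney, was lower (9 of 9 arms negative, 2 past the test over all and 2 over the list alone, camera adjusted p = 0.0400; adjusted p = 0.241 with an estimated correlation) with miR-30a at -2.33 (SE 0.49) and miR-30a* at -3.24 (SE 0.72). In the muscle and heart list 12 of 15 arms were negative and 1 fell, miR-206-2* (-1.20, SE 0.31; 1 over the list alone; camera adjusted p = 0.0400; adjusted p = 0.203 with an estimated correlation), while miR-1 stood at 0.93 (SE 0.43), miR-133a at -0.19 (SE 0.48) and miR-206 at 0.27 (SE 0.48). The calls of these 3 lists were thus lost with an estimated correlation. The miR-30 call also ended without 36 hpf DMSO replicate 1 (0.102) and 60 hpf DMSO replicates 2 and 3 (0.0678 and 0.0766), and the muscle and heart call without 36 hpf DMSO replicate 3 (0.130) and 60 hpf DMSO replicate 2 (0.0658). miR-92b itself passed neither without 36 hpf DMSO replicates 2 and 3 (0.0600 and 0.118) nor without 60 hpf DMSO replicates 1 and 2 (0.0733 and 0.0832).

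Neural miRNAs went both ways from 36 to 60 hpf. Of 26 arms 6 rose and 1 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.0775, fry 6.6e-06). Those that rose included miR-9-1* (2.73, SE 0.32), miR-129-1* (1.93, SE 0.29), miR-124-4* (1.81, SE 0.48) and miR-137 (1.73, SE 0.39), and the one that fell was miR-219-3* (-2.41, SE 0.68). The call of miR-219-3* ended without 36 hpf DMSO replicates 2 and 3 (0.0652 and 0.0745) and 60 hpf DMSO replicate 1 (0.0849). In the list linked to the aryl hydrocarbon receptor 4 of 11 arms rose with development (5 rose and 1 fell adjusted over the list alone), namely miR-132 (2.26, SE 0.56), miR-132-1* (1.98, SE 0.52), miR-132-2* (2.20, SE 0.53) and miR-212* (2.91, SE 0.90), which form a neuronal cluster. Its median was 0.03 (-0.06 and -0.23 with RLE and upper quartile scaling), its mean 0.76 and its camera adjusted p 0.351, while fry called it (0.00736). In the endocrine list 2 of 9 rose, miR-7a-1 (1.72, SE 0.37) and miR-7a-3 (2.12, SE 0.31), and in the smooth muscle list 1 of 3, miR-145 (0.89, SE 0.26), or 3 of 3 adjusted over the list alone. The camera adjusted p of these lists was 0.263 and 0.179, and fry called both (0.000673 and 0.000584). miR-210* (-0.91, SE 0.24) fell among the 12 stress, p53 and hypoxia arms, also adjusted over the list alone. That list's median was 0.35 and its camera direction down (adjusted p = 0.912). None of the 9 endothelial, 11 leukocyte, 4 erythroid, 16 epithelial, 17 Hox cluster, 11 cartilage and 20 cluster arms of the miR-23a, miR-24 and miR-27a list passed, with list medians of -0.06, -0.38, 0.42, -0.31, -0.51, 0.12 and -0.25 and camera adjusted p of 0.351, 0.179, 0.836, 0.179, 0.145, 0.912 and 0.179. The endothelial median was positive with total count scaling (0.11) and the cartilage median negative with upper quartile scaling (-0.17). The erythroid median of 0.42 stood against a mean of -0.03 and a camera direction of down.

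In TCDD embryos the same developmental comparison gave 88 calls, 52 higher and 36 lower at 60 hpf, and DESeq2 136. The smallest p-values belonged to let-7d (3.42, SE 0.38), miR-190b* (5.91, SE 0.75), let-7a (3.01, SE 0.39), miR-190b (4.94, SE 0.63) and miR-183* (1.96, SE 0.26). In the let-7 timing list 17 of 35 arms rose, in the miR-430 family 8 of 8 fell, in the muscle and heart list 4 of 15 fell and in the miR-17-92 type list 4 of 32 fell. Of the calls in DMSO embryos, 37 of 52 higher and 18 of 23 lower were also calls in TCDD embryos, where independent lists would share 6.59 and 2.02. The number of calls fell to 58 without 36 hpf TCDD replicate 2. Total count scaling moved the median of all miRNAs by 0.46 in TCDD embryos and gave 110 calls, 90 higher and 20 lower (81.8% higher against 59.1%). Keeping the transcript features in the scaling moved the median by 0.45 in DMSO and 0.76 in TCDD embryos and gave 80 higher and 12 lower calls in DMSO and 137 and 17 in TCDD embryos. In DMSO embryos upper quartile scaling moved it by -0.28 and total count scaling by 0.12, and the upper quartile gave 36 higher and 30 lower calls (54.5% higher against 69.3%).

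No measure of library composition passed a test between treatments with adjustment over the 4 measures. Star arms took 10.5% ± 0.407 of miRNA counts in TCDD and 7.12% ± 0.132 in DMSO embryos at 60 hpf (SD, n = 3 each; exact two-sided permutation p = 0.10, the smallest that 3 against 3 allow). At 36 hpf the shares were 7.64% ± 0.827 and 7.56% ± 0.862 (exact permutation p = 0.700). Over both times the mean difference was 1.73 percentage points (stratified exact permutation p = 0.0350 over 400 relabellings, adjusted p = 0.140 over the 4 measures of composition), and the difference between the times was 3.28 points (p = 0.0700). These relabellings, like those of Pearson's r above, permute each time by itself and do not account for the pairing of TCDD libraries of one number between the times. Without 1 library the p of the mean difference over both times was 0.055, 0.065, 0.060, 0.050 and 0.050, for 36 hpf DMSO replicates 1 and 2, 36 hpf TCDD replicate 3 and 60 hpf DMSO replicates 1 and 3 in turn. Total counts, miRNAs detected and the share of the 10 most abundant miRNAs had stratified permutation p-values of 0.425, 0.650 and 0.700.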

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

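The tests of miR-27e, of the miR-19 arms and of the TCDD libraries that share a number were chosen only after those results were seen, whereas the counts over other splits of the libraries were planned.

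The effect of TCDD on the cartilage and mesenchyme list differed between the times by camera at its preset correlation (adjusted p = 0.0336), but not with an estimated correlation (adjusted p = 0.488) or by fry (0.213). The list median was -0.14 at 36 hpf and 0.45 at 60 hpf, neither of them a call. The list test of the difference was not planned, and camera was not repeated on it with libraries left out. Among the transcript features kept apart from the miRNAs, ENSDART00000118558 was higher in TCDD embryos at 60 hpf (log2 fold change 3.69, SE 0.40, edgeR adjusted p = 0.00101) and over both times (2.01, SE 0.28, adjusted p = 0.0119). ENSDART00000116254 was higher over both times (3.48, SE 0.59, adjusted p = 0.0219). They stood out as signals outside the main measurement, and neither identifier was found in the reference tables used here. Of 427 such features tested with edgeR beside the miRNAs, 0 were called at 36 hpf, with 33 at unadjusted p under 0.05. There were 53 such features at 60 hpf, 32 over both times and 49 for the difference between times.

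Each comparison was repeated over other splits of its libraries. A comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. For TCDD at 36 hpf the real split called 0 miRNAs and 0 lists and the highest other split 1 and 1, so all 10 splits gave as many of each by necessity. For TCDD at 60 hpf the real split called 1 miRNA and no other split any (1 of 10 gave as many), while for lists the real split called 1 and the highest other 3 (4 of 10). Over both times 4 of 100 splits gave as many miRNAs as the real 1 (highest other 2), a share under 0.05. These splits are fewer than the 400 relabellings possible over both times. They also relabel each time by itself although TCDD libraries of one number deviated alike at both times. The share is thus not exact. limma-voom with that pairing kept the call (adjusted p = 0.0221). For the lists over both times 31 of 100 splits gave as many as the real 1 (highest other 3), so chance is not excluded. For the difference between times the real split called 0 miRNAs, so all 100 splits gave as many by necessity (highest other 3), and the count says nothing about chance. For development in DMSO embryos the real split called 75 miRNAs and 7 lists and the highest other 1 and 6 (1 of 10 each), and in TCDD embryos 88 miRNAs and the highest other 0 (1 of 10).

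For the rise of miR-27e with TCDD at 60 hpf, a fixed share of reads of miR-27a to miR-27d counted on it is argued against. The log2 ratio of miR-27e to the sum of these paralogs differed by 2.31 between TCDD and DMSO. The ratios were 0.0889 to 0.129 in DMSO and 0.259, 0.282 and 2.23 in the TCDD libraries, the last where miR-27c was nearly absent. Without that library the difference was 1.30. A share that differs between TCDD and DMSO libraries was not tested. The paralogs were already known not to pass when this ratio was chosen. A single library carrying the rise is argued against too, as the lowest TCDD library lay 3.84 times above the highest DMSO library. The minor arm miR-27e* was 1.53 higher over both times on the log2 scale (SE 0.33, unadjusted p = 0.000778 by edgeR, adjusted p = 0.113), which goes with more of the hairpin in TCDD embryos over both times. At 60 hpf alone miR-27e* was at 1.07 (SE 0.45, adjusted p = 0.656) against 2.26 (SE 0.34) for miR-27e, and the difference between times was -0.92 (SE 0.66) for miR-27e* and 1.42 (SE 0.47) for miR-27e, neither past the test. More of the miR-27e hairpin may thus be a part of the rise, a hypothesis found and tested on the same libraries, and how much of the rise at 60 hpf it covers stays open.

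The major arms miR-19a to miR-19d were lower in value in TCDD embryos at 60 hpf (mean log2 fold change -1.80, with SEs of 0.48 to 0.74 for the single arms), though none passed edgeR's quasi-likelihood test, and in 60 hpf TCDD replicate 3 miR-19b (1843 CPM) and miR-19d (158 CPM) lay far below every other library (26367 and 2312 CPM or more). Without that library their mean was -1.33. Whether there were fewer miR-19 hairpins is open. The 4 minor arms had a mean of -0.14 (SE over arms 0.23, single arms 0.35 to 0.68). That lay more than 2 SE over arms above 0.5 times -1.80, the mark set against fewer hairpins. Without 60 hpf TCDD replicate 3 their mean was -0.22 (SE over arms 0.27), which is not 2 SE above 0.5 times -1.33. The outcome thus rested on that library, and an SE over arms does not measure the spread between libraries. Less the median of all arms with a star (0.11) the mean of the minor arms over all libraries was -0.25. Less the median of all arms without a star (-0.12) that of the major arms was -1.68. Whether the whole miR-17-92 type clusters were lower is open too. miR-17a, miR-18a, miR-20a and miR-92a had a mean of -0.50 (SE over arms 0.39, single arms 0.59 to 1.23). A step that acts on the mature arm or on its capture in the library could leave the minor arms as they were, and was not tested apart from TCDD.

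TCDD libraries of the same number deviated alike from their group means at 36 and 60 hpf, though a chance match of the numbers was not tested. This shared deviation correlated between the arms of 117 hairpins at only 0.12 (bootstrap SE 0.052), where the developmental change correlated at 0.73, a share of 16.4%. Embryo batches that move both arms together as development did are thus argued against. The TCDD effects themselves correlated between arms at only 0.05 (36 hpf) and 0.23 (60 hpf), so other differences between embryo batches stay open. Noise that hides a joint movement of both arms is argued against as well: opposite arms correlated at 0.0273 between the times and the same arm at 0.316. A library step that acts on single RNA sequences may have been shared by libraries of the same number, which these values go with. They do not tell such a step from embryo batches that differ in single arms. Hairpins are not independent replicates.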

How the results depend on the processing

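Counting every hairpin copy, keeping the transcript features and leaving out both TCDD libraries numbered 3 were settings chosen only after the data were seen. So were taking TCDD libraries of one number as correlated and setting the block within each treatment. Summing the copies was the counting rule written before the data were examined, and became an alternative when that rule was replaced. No named miRNA and no list reversed its direction past the test under any setting run. Of the comparisons of a named miRNA with an alternative, 1625 stayed on the same side of the threshold, 51 lost the call and 32 gained one, and of those of a list 891, 26 and 14. The main results, such as the counts of calls, were less stable. Of their comparisons 205 stayed the same, 62 moved, 5 were weaker and 1 was stronger. A count moved if it changed by more than 1.5 times or to or from none. At a depth of 459634 to 4210840 counts and 3 libraries per group, most simulated 2-fold changes were missed and most 4-fold ones were found. That simulation changed many miRNAs at once, so a smaller share would be found where only a few change. The cause of the changes listed here was not tested, except that fewer libraries or summed families leave fewer values to test.

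DESeq2 called 10 miRNAs for TCDD at 60 hpf, 4 over both times, 6 for the difference between times, 120 for development in DMSO and 136 in TCDD embryos. The likelihood ratio test called 5 at 60 hpf, 4 over both times and 1 for the difference, and the exact test 5 at 60 hpf. With only the groups compared there were 0 calls at 60 hpf and 54 for development in TCDD embryos. The replicate block, which pairs TCDD with DMSO libraries of one number within each time, gave 0 at 60 hpf and 0 over both times; it does not account for the pairing of TCDD libraries between the times. limma-voom with that pairing gave 1 call over both times and 0 for the difference. Counts summed per family gave 0 at 60 hpf, 0 over both times, 29 for development in DMSO and 34 in TCDD embryos. Every copy as a feature gave 261 (106 higher, 155 lower) and 275 for development, since a family of many copies then counts many times. With transcript features kept there were 2 calls at 60 hpf and 154 for development in TCDD embryos. Without both TCDD libraries numbered 3 there were 0 calls at 60 hpf and 0 over both times, and 0 lists for each.

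For lists, an estimated correlation gave 0 calls at 60 hpf, 0 over both times and 0 for development in DMSO embryos. fry gave 2, 0 and 11, and the replicate block 0 over both times. With 1 library left out at a time, the calls ran from 0 to 1 (TCDD at 60 hpf), 0 to 2 (both times), 0 to 2 (difference) and 58 to 82 (development in TCDD), and the lists from 0 to 1 (36 hpf), 0 to 3 (60 hpf) and 0 to 2 (both times). The correlation of the TCDD effects ran from 0.0428 to 0.368, and the difference in the share of star arms from 1.5 to 1.96 percentage points.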

Other observations

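The correlation of arms and the search for nearly absent arms were chosen only after the data were seen. Across 117 hairpins with both arms at 10 CPM or more, the log2 fold changes of the major and minor arm from 36 to 60 hpf correlated at 0.73 (bootstrap SE 0.065) in DMSO and 0.66 (SE 0.072) in TCDD embryos. For TCDD against DMSO the arms correlated at 0.05 (SE 0.10) at 36 hpf and at 0.23 (SE 0.085) at 60 hpf. Hairpins are not independent replicates.

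Some arms were nearly absent from 1 or 2 libraries, at least 10-fold below the lowest of the remaining libraries where that was at 20 CPM or more. There were 11 such cases over 9 arms, 10 of them in TCDD libraries and 1 in 60 hpf DMSO replicate 2 (miR-15b*). In 60 hpf TCDD replicate 3, miR-19b stood at 1843 CPM against 26367 CPM or more in the other libraries, and miR-19d at 158 CPM against 2312 CPM. The neural miR-124 was at 20.7 CPM in 60 hpf TCDD replicate 2 against 250 CPM or more elsewhere, and the hypoxia-linked miR-210 was low in both TCDD libraries numbered 2 (45.8 CPM at 36 hpf and 38.1 CPM at 60 hpf, against 485 CPM). miR-27c was at 0 in 36 hpf TCDD replicate 2 and at 2.57 CPM in 60 hpf TCDD replicate 1, against 39.7 CPM. The opposite arm was not low in any of the 8 arms where it was compared. For miR-124, whose opposite arms are separate features by hairpin copy, it was not compared.

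Among transcript features, 97 of 427 were called for development in DMSO embryos (8 higher, 89 lower at 60 hpf) and 232 in TCDD embryos (18 higher, 214 lower). The test of the difference between these 2 developmental changes called 0 of 427, so the unequal counts do not show that TCDD altered the change. As a class the transcript features took 2.24% to 5.35% of the counts at 36 hpf and 1.20% to 1.65% at 60 hpf. How far the balance of higher and lower calls depends on this or on the scaling used was not tested.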
